A study of Sus scrofa and Mus musculus with 6 samples.

How the data were processed

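Gene expression was measured on 3 Agilent 2-colour arrays that carried 6 samples. Each porcine array carried RNA of 1 induced pluripotent stem (iPS) cell clone in Cy5 and RNA of the parental embryonic fibroblasts (PEF) in Cy3, per the labels. The mouse array carried embryonic stem (ES) cell RNA in Cy5 and embryonic fibroblast (MEF) RNA in Cy3, per the labels. Each labelling reaction used 400 ng of total RNA, and all cells were grown in DMEM with 10% serum, per the labels' protocols. The labelling protocol calls the porcine Cy5 RNA that of differentiated iPS cells, whereas the sample labels name iPS clones; which wording applies is not given in the sources used here.

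The spot intensity and local background intensity values were made with Agilent Feature Extraction 9.5.3.1, per the file headers. The processed intensity of each channel had been background-subtracted and dye-normalized by that program, per the file headers. The deposited value tables hold values on a log10 scale. Each porcine column was the log10 processed intensity of its own channel shifted by 1 constant, with the 75th percentile at 1750 intensity units. The column medians were 2.17 for clone 1, 2.17 for PEF on array 1, 2.16 for clone 2 and 2.16 for PEF on array 2 on the log10 scale. The mouse columns had medians of 2.05 (ES) and 2.02 (MEF) and the same 75th percentile, but they were not shifted copies of the mouse scanner values. How the mouse table was made, and from which scan, stays unknown.

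The median spot intensities were background-corrected with normexp (offset 50) on the median local background and normalized by loess within each array, in limma 3.58.1 under R 4.3.3. The design written before the data were examined named the mean spot signal; the median was used because the files give the median. Control spots took part in normexp, had weight 0 in loess and were then left out, as were spots with an outlier flag. Spots of 1 probe were averaged. A probe was tested if it was well above background in at least 1 channel of every array of its species. This kept 28179 of 38721 porcine probes and 27213 of 39429 mouse probes. No spot was saturated.

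The porcine comparison tested the mean log2 ratio of the 2 arrays against 0 with limma (lmFit and eBayes), with Benjamini-Hochberg adjusted p under 0.05. The array was a block built into each ratio, because each iPS sample and its PEF sample shared an array. Deviations of the iPS and PEF channels from their group means correlated within arrays at r = 0.36 across probes. The PEF channels may hold 1 RNA extract, so the test against 0 leaves out the control's own spread. The labels do not say that the clones or the fibroblast samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Both porcine arrays lay on 1 slide and were scanned once, so slide and scan did not differ between them. Dyes were not swapped, so a probe's own dye bias is part of every ratio. The mouse comparison had 1 array and no test, and counts past 4-fold are given.

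A probe well above background in only 1 group has a bound: the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. These bounds used channel values after loess and Aquantile and are open to dye bias.

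Porcine probes carry only design identifiers and mouse probes carry transcript identifiers, and the tables used here do not pair them with genes. The 30 gene lists fixed before the data were examined therefore matched 0 probes, and the planned list tests and the comparison of porcine with mouse genes were not run. The analysis was made on probes, and the 2 highest and 2 lowest probes by log2 ratio are named in each comparison, a shortened form of the planned rule of 6 per direction by gene symbol. For the porcine comparison these had to pass the test with the same sign on both arrays. For the clone comparison the PEF channels had to differ by less than 1 on the log2 scale.

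The porcine test was checked on simulated data for the 28179 porcine probes, with 50 changed probes at each of 4 sizes. It recovered 18% at a log2 change of 0.5, 96% at 1, 100% at 2 and 100% at 4, and called 12 of 27979 unchanged probes. The simulation held far fewer changed probes than the 22827 called in the data, which alters the adjusted p. It also drew variances from the fitted prior and gave probes no dye bias of their own. These rates therefore check the procedure and are not error rates of the porcine results. The number of arrays limits the precision of every comparison. Alternatives were Agilent's processed signals, the value tables, normexp with offset 0, no background correction, median centring in place of loess, no filter, a filter on both channels, outlier spots kept, a trended variance prior, separate channels with no replicate block, other size thresholds, and leaving out each sample.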

Results

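The data were 3 arrays: 2 porcine arrays, each with 1 iPS clone against parental PEF, and 1 mouse array with ES cells against MEF. iPS cells are somatic cells returned to a pluripotent state, and ES cells are pluripotent cells taken from the early embryo. On the porcine arrays, 70.9% of the 38721 probes were well above background for clone 1 and 69.8% for clone 2, beside 68.6% and 69.3% for PEF. On the mouse array, 65.9% of spots were well above background in Cy5 and 67.4% in Cy3. The median spot signal above local background was 110 and 115 intensity units for the porcine clones. It was 115 in Cy5 and 94 in Cy3 on the mouse array. In the authors' deposited scanner statistics, the spike-in log ratios had slopes of 0.868 and 0.875 against their known values on the porcine arrays and 0.885 on the mouse array.

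The first comparison asked how the porcine iPS clones differed from the fibroblasts they came from. Probe AGPOA4-06165 had the highest ratio, with a mean log2 iPS over PEF of 8.46 ± 0.085 (SD, n = 2 arrays). Probe AGPOA4-28114 followed at 8.09 ± 0.16. Probe AGPOA4-23846 had the lowest ratio at -9.23 ± 0.048, followed by AGPOA4-03809 at -8.40 ± 0.13. All 4 probes were well above background in both groups on both arrays, and each had a limma adjusted p of 1.59e-06. Their genes are not named here, because the files used give porcine probes by identifier alone.

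Across the array, 22827 of 28179 probes passed the limma test, 11036 higher and 11791 lower in iPS cells. Of these, 8796 differed by at least 2-fold, 3657 higher and 5139 lower. At least 4-fold, 3190 probes passed, 1080 higher and 2110 lower. At least 16-fold, 554 passed, 163 higher and 391 lower. The median absolute log2 ratio of the probes that passed was 0.77, against a median standard error of 0.067 (n = 2 arrays). The balance of directions depended on the scaling. With median centring in place of loess the split became 13863 higher and 8944 lower, with 6276 and 3812 at 2-fold and 1914 and 1500 at 4-fold. With processed signals it was 11915 higher and 10379 lower, and 6266 probes passed at 4-fold, 2700 higher and 3566 lower. Dyes were not swapped, so every ratio includes the dye bias of its probe.

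Some probes were well above background in 1 group only. There were 1629 such probes for iPS cells on both arrays, of which 1423 passed the limma test. There were 1323 for PEF, of which 1252 passed. Of the iPS probes, 108 were at least 4-fold higher in iPS cells by their bound and 20 at least 16-fold. Of the PEF probes, 102 were at least 4-fold lower in iPS cells by their bound and 19 at least 16-fold.

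The second comparison set the clones against each other. The log2 ratios of the clones correlated across 28179 probes with Pearson's r of 0.987 and Spearman's rho of 0.980; probes are not independent replicates. Unchanged samples simulated against 1 shared control gave r = 0.489. That value follows from giving all simulated samples equal noise. The covariance was 1.75 against 0.00634 simulated, a difference of 1.74. The simulated noise was set from the difference between the PEF channels. It therefore leaves out whatever both PEF channels share and any dye bias of a probe, and the difference of 1.74 may include both. At 4-fold or more, 987 probes were higher in iPS cells on both arrays, where independent lists of 1107 and 1088 probes would share 42.7. In the other direction 1960 were shared, from lists of 2114 and 2141, where independent lists would share 161. Part of this excess may come from the shared fibroblast control.

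**Figure D1:**
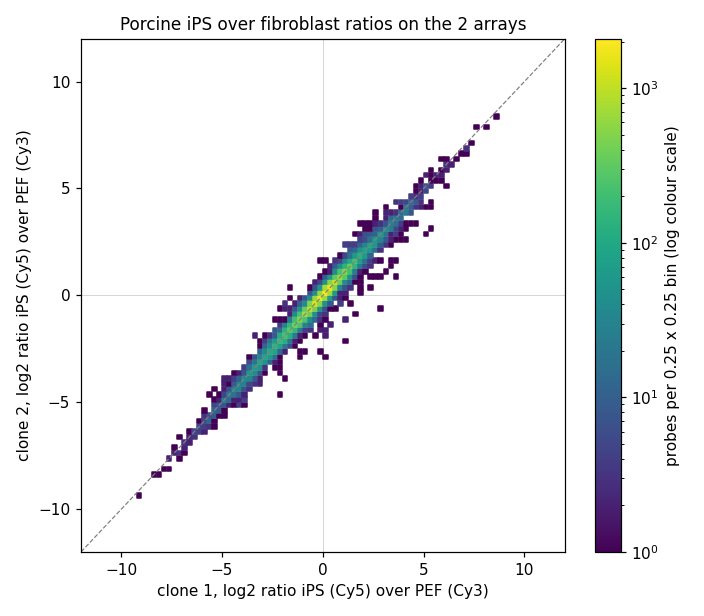
Each square is a bin of porcine probes, placed by the log2 ratio of iPS over PEF for clone 1 (horizontal) and clone 2 (vertical), with colour giving the number of probes on a log scale; the dashed line marks equal ratios. The probes lie along that line, with r = 0.987 over 28179 probes.

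The clones differed by at least 4-fold at 12 probes, all 12 with the higher ratio in clone 1. Under every setting more of these probes were higher in clone 1, but the count and how one-sided it was changed with some settings. With processed signals it was 125, of which 91 were higher in clone 1 and 34 in clone 2. With offset 0 it was 38, of which 33 and 5, and with no background correction 11, of which 11 and 0. Probe AGPOA4-31372 had a log2 ratio of 2.88 in clone 1 and -0.58 in clone 2, a difference of 3.47. Probe AGPOA4-13795 had 1.12 and -2.23, a difference of 3.34. The lowest differences, with the higher ratio in clone 2, were -1.90 at AGPOA4-23410 and -1.73 at AGPOA4-22457. At all 4 probes the PEF channels differed by at most 0.11 on the log2 scale. Measured the same way, the iPS channels differed by at least 4-fold at 14 probes and the PEF channels at 0. At 2-fold or more the counts were 137 and 14. The SD of the difference was 0.22 for the iPS channels and 0.11 for the PEF channels. The iPS channels were all Cy5 and the PEF channels all Cy3. Among the E1A control probes, averaged over 32 spots each, E1A_r60_a107 changed most in Cy5 between the porcine arrays. Its normalized log2 values on arrays 1 and 2 were 8.364 and 8.276 in Cy5 and 10.245 and 10.211 in Cy3. Cy5 noise as large as 4-fold was thus not seen at these controls. They are few and averaged over spots, so they cannot show rare noise at single spots. A difference between the clones therefore cannot be told apart here from such noise in Cy5. Each clone was 1 sample on 1 array, so no test of the clones was made.

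**Figure D2:**
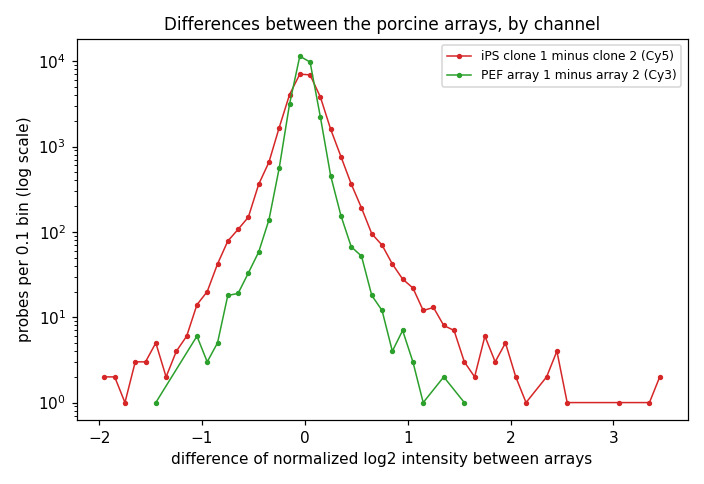
The lines give the number of porcine probes (log scale) in each bin of the difference in normalized log2 intensity between the arrays, for the iPS clones in Cy5 and for PEF in Cy3. The iPS distribution is wider, with SD 0.22 against 0.11, and extends past 2 on the side of clone 1.

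The third comparison was mouse ES cells against MEF. Its direction is not settled. The scanner file with the dyes stated in the labels and the value table with its sample names gave opposite ratios, with r = -0.81 across 27213 probes. Either the stated dyes of the scan or the names of the table columns may be exchanged, so no mouse count here has a settled direction, and counts are given under both signs. In the scanner file, 821 probes differed by at least 4-fold, 169 with Cy5 higher and 652 with Cy3 higher. The processed signals of the same file gave 2523, 665 with Cy5 higher and 1858 with Cy3 higher, and median centring gave 431 and 479. Read by the labels, Cy5 is ES; read by the value table, the channels stand the other way round. In the value table, 2423 of the same probes differed by at least 4-fold, 1923 with the ES column higher and 500 with the MEF column higher. Both sources passed 4-fold at 747 probes with opposite sign and at 0 with the same sign. With 1 array there is no replicate check; the log2 ratio had a median SD of 0.046 over the 10 spots of repeated probes.

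**Figure D3:**
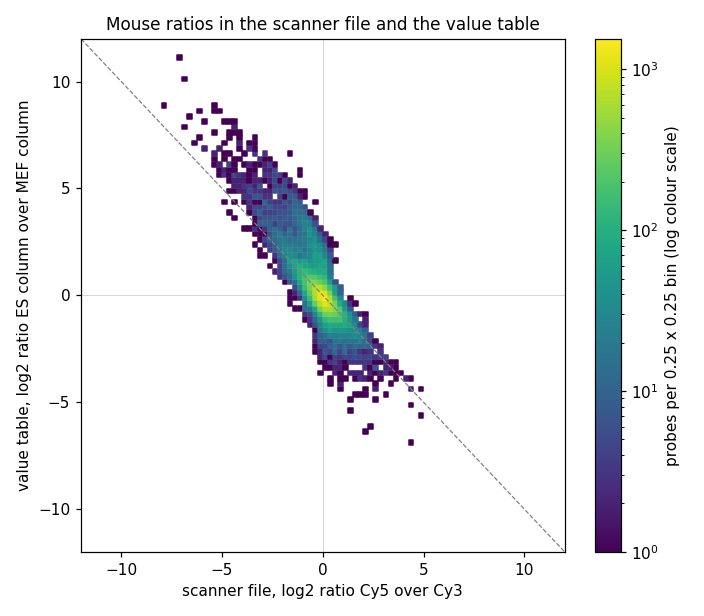
Each square is a bin of mouse probes, placed by the log2 ratio of Cy5 over Cy3 in the scanner file (horizontal) and of the ES over the MEF column in the value table (vertical), with colour giving the number of probes on a log scale; the dashed line marks equal size and opposite sign. The cloud slopes the same way as that line, with r = -0.81, but is steeper: the SD was 1.22 in the value table and 0.78 in the scanner file. Among probes with the ES column higher, a further arm lies off the line, with smaller scanner ratios than table ratios.

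The mouse probes with the highest Cy5 over Cy3 were A_55_P2007964 (transcript NM_009987), at a log2 ratio of 4.85, and A_55_P2044932 (NM_030720), at 4.83. In the value table their ES over MEF ratios were -5.62 and -4.38. The lowest was A_51_P413376 (NM_009556) at -7.81, where the value table gave 8.82. Probe A_55_P2088550 (NM_001162933) was not well above background in Cy5. By its bound after loess it was at least 134-fold brighter in Cy3, at a log2 ratio of -7.06. With median centring its log2 ratio was -6.72, so the bound holds for the main setting only. The value table gave 11.04. Among transcript classes, 3.32% of the 20476 tested probes for RefSeq mRNAs differed by at least 4-fold (95% exact binomial interval 3.08 to 3.58%). For probes of RefSeq non-coding RNAs the share was 3.84% of 677 (2.52 to 5.58%), and these intervals overlap. For probes outside the RefSeq and Ensembl classes the share was 1.67% of 4188 (1.31 to 2.11%), below the interval of RefSeq mRNAs. Of the probes in that class 52.3% were tested, against 77.0% for RefSeq mRNAs and 48.4% for RefSeq non-coding RNAs. Signal level was not matched between classes. Ensembl transcripts had 2.15% of 1257 (1.42 to 3.11%), predicted RefSeq mRNAs 3.24% of 340 (1.63 to 5.72%) and predicted RefSeq non-coding RNAs 2.55% of 275 (1.03 to 5.17%). In the value table the shares were larger: 9.30% for RefSeq mRNAs, 11.8% for RefSeq non-coding RNAs, 8.82% and 11.6% for the predicted mRNAs and non-coding RNAs, 8.99% for Ensembl transcripts and 6.30% for the rest. Predicted non-coding RNAs thus lay below RefSeq mRNAs in the scanner file and above them in the value table, with overlapping intervals in both. These shares compare unlike processing, since those of the scanner file used normexp with its offset and loess. Over all tested probes, 3.02% differed by at least 4-fold in the scanner file and 8.90% in the value table. With the processed signals of the scanner file it was 9.27%, so the larger shares may come from the processing. Shares by class with processed signals are not given here, so the change in order cannot be assigned to the source. All intervals treat the probes of 1 array as independent, which they are not. Of 186 transcripts that had several tested probes and at least 1 probe past 4-fold, 124 had all probes at 2-fold or more in 1 direction. In 0 did another probe differ by 2-fold or more the other way.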

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

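All tests of explanations in this part were chosen after the results were seen. At 3 porcine probes the clones moved in opposite directions against PEF by at least 2-fold each, and the difference was not tested, since each clone was 1 sample. Clone 1 minus clone 2 was 2.23 at AGPOA4-04451, 2.34 at AGPOA4-23979 and 3.34 at AGPOA4-13795 on the log2 scale; these probes were named after their values were seen.

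Control probe ETG09_35454, which the comparisons did not use, was well above background in Cy5, the iPS channel, at 20 of 20 spots on the porcine arrays and at 0 in Cy3. A Cy5 background raised on control spots in general is argued against, since 0 of the 24 other ETG and RC control probes showed such signal. An RNA of the iPS samples that binds the probe may be the source, and this cannot be told apart from a dye effect of the probe, because 0 arrays carried iPS RNA in Cy3. On the mouse array the same probe was well above background in Cy5 at 1 of 10 spots, so Cy5 alone did not light it there; a dye effect limited to the porcine slide is not excluded by 1 array. Also on the mouse array, control probe ETG05_66023 was well above background in Cy3 at 10 of 10 spots and in Cy5 at 3.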

How the results depend on the processing

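Every alternative reported here was chosen before the data were examined, and where a value moved the cause was not tested unless stated. The 4 named porcine probes kept their direction under each alternative and their call under each that kept all samples. Single arrays had no test. Among alternatives that kept all samples, the porcine total stayed within 1.5 times of 22827 except with the added 2-fold requirement. That requirement by construction left 8796 (3657 higher, 5139 lower). With no replicate block, 22108 probes passed (10649 higher, 11459 lower), and 21991 were called with and without the block. The fit with no block counts the PEF channels as separate samples, though they may hold 1 RNA extract. Leaving out 1 sample in that fit left a lone sample, which was assumed to vary like the other group. With a clone left out, all spread came from the PEF channels and may be technical. Counts of probes passing in these fits are therefore not given.

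Processed signals gave 13419 porcine probes at 2-fold or more (6706 higher, 6713 lower) and 6266 at 4-fold or more (2700 higher, 3566 lower). The value table, a shifted copy of the same signals, gave 13480 (6857 higher, 6623 lower) and 6247 (2739 higher, 3508 lower). With offset 0, 1763 probes were at 4-fold or more and higher. Median centring turned the majority from lower to higher at 2-fold (6276 higher, 3812 lower) and at 4-fold (1914 and 1500). The higher share of all calls was 48.3%, and it was 60.8% with median centring, 53.4% with processed signals and 54.3% with the value table.

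The clones differed by 4-fold at 125 probes with processed signals, 126 with the value table (92 higher in clone 1, 34 in clone 2) and 38 with offset 0, and by 2-fold at 98. Their r was 0.976 with processed signals and by construction the same with the value table, whose porcine columns are those signals shifted by a constant. It was 0.981 with offset 0, 0.988 without background correction and 0.986 with median centring. With no filter it was 0.985, and with the filter on both channels 0.988.

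The mouse count at 4-fold was 2523 with processed signals (665 Cy5 higher, 1858 Cy3 higher), 1480 with offset 0 (292 and 1188) and 2423 in the value table (1923 with the ES column higher). Median centring gave 431 with Cy5 higher and 479 with Cy3 higher. At 2-fold it was 3523 (1247 and 2276). The value table reversed the 4 named mouse probes, to -5.62 for A_55_P2007964, -4.38 for A_55_P2044932, 8.82 for A_51_P413376 and 11.04 for A_55_P2088550. Leaving out saturated probes removed none, and averaging the probes of a gene was not run, since probes carried no symbols. Signal over background limits dim probes: the offset of 50 narrows their ratios.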

Other observations

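All tests in this part were chosen after the results were seen. The mouse ratios of the scanner file and the value table ran opposite ways. A shifted copy of this scan's processed signals with the channels exchanged is argued against: the ES column minus the Cy3 processed signal had an SD of 0.176 on the log10 scale, where each porcine column matched its channel to a constant. Another extraction or normalization of this scan with an exchange is not excluded. The ES column correlated across spots at 0.991 with Cy3 and 0.967 with Cy5, and the MEF column at 0.987 with Cy5 and 0.962 with Cy3. Whether the table comes from another hybridisation stays open: over repeated spots, deviations in scan and table correlated at up to 0.399, below the 0.564 between the channels of the scan but close to the 0.432 between the columns of the table. The 95% bootstrap interval of the latter difference ran from -0.062 to 0.14. Whether sample names are exchanged in 1 of the sources stays open. The gene lists could not decide it: they hold gene symbols, whereas the mouse probes carry transcript identifiers. The 0 pluripotency list members matched to a mouse probe follow from that and say nothing about the names. No biological explanation was tested.

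The mouse log2 ratios had an SD of 0.78, against 1.33 on the porcine arrays. Narrowing by the offset of 50 as the whole cause is argued against, since the mouse SD over the porcine SD was still 0.656 with processed signals and 0.584 with the offset. Compression of ratios on the mouse array as a whole is argued against, since its spike-in slope over the lower porcine slope was 1.02. Different probe sets and a real difference between the cell pairs stay open and untested.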
